A study of Zea mays with 4 samples.

How the data were processed

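Gene expression was measured in maize (Zea mays) roots on 4 spotted oligonucleotide arrays, each hybridised with RNA from nitrate-treated roots labelled with Cy3 and RNA from control roots labelled with Cy5, per the labels. The arrays came in 2 versions, A and B, with different probe sets and 2 replicate arrays each. All 4 arrays had the same dye orientation, so a gene-specific dye effect stays in every ratio. Series text gives 2 biological replicates per treatment, but the column headers leave open whether the control RNA of both replicates came from separate plants. The spread between these arrays may thus in part be technical. The limma p-values rest on this spread and on a spread pooled over probes.

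The deposited intensity of each spot is a whole number per dye on a linear scale, with some values below 0. The authors had therefore already subtracted a background, by a method not given in the sources used here. The deposited ratio is nitrate over control on a linear scale. Its median was between 0.996 and 1.01 on the 4 arrays, so the authors had normalized it within each array, also by a method not given in the sources used here. The value table of the series differed from this ratio column by less than 0.0001 on 100% of the spots of each array. Its log2 correlated at 0.811 to 0.925 with the log2 ratios of nitrate over control computed from the intensities, which gives its scale and direction.

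Each array had 32448 spots in 48 blocks. Version A held 28830 maize probe spots and version B held 27477. Log2 ratios were computed from the deposited intensities with limma 3.58.1 in R 4.3.3, by normexp with an offset of 50 and global loess within each array. Control spots had weight 0 in the loess and were left out of the tests. The same was done with 4 to 10 spots per array that carry a flag B in the deposited files, read as bad quality, a meaning not given in the sources used here. Spots of a probe were averaged. The planned filter on dim spots needed the local background and its SD, which are not used here because the deposited intensities are already background-subtracted, so a channel was instead called above background when it exceeded the 95th percentile of the buffer and blank spots of its array. A probe was tested when at least 1 channel passed on both arrays, which left 28374 probes on version A and 24748 on version B. This rule differs from the planned one.

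For each version the mean log2 ratio was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment over the probes of that version and a threshold of 0.05. With 2 arrays there is 1 residual degree of freedom, and the rest of the test comes from the prior. Probes at least 2-fold the same way on both arrays were also counted, without a test. Gene lists fixed before the data were examined (27 of them) were tested with camera at a preset correlation of 0.01, on both versions stacked by replicate number, with the brightest probe of each of 33267 genes, where probes with the same top protein hit count as 1 gene, and near-identical genes or hits of 1 gene in 2 species are not resolved. The brightest probe is that with the highest mean log2 intensity over both channels and arrays. Camera at the preset correlation compares the genes of a list with all other genes. Its p rests on the spread between genes and does not measure the spread between replicates. Members were also counted with their limma calls over all probes and adjusted over the list alone. The adjustment over a list alone does not cover the other lists, and in a small list it is close to an unadjusted p. At an unadjusted limma p under 0.05 there were 3415 of 28374 probes on version A and 3202 of 24748 on version B.

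The fit and the list test were tried on simulated log ratios, 20 draws per version with 200 changed probes. Changes of up to 8-fold were equal on both simulated arrays, and noise was independent between probes, with its spread drawn from the fitted prior. Normalization, dye and replicate effects were not simulated. The called shares thus hold for this simulation and may overstate what the real arrays could detect. For version B (24748 probes) limma called 98.3% of simulated 4-fold changes and 21.6% of 2-fold changes on average, and for version A (28374 probes) 92.7% and 6.29%. The false share of the calls averaged 12.5% for version A, with a range of 5.15% to 30.5%, and 13.3% for version B, with a range of 2.33% to 37.1%, against the nominal 5%. The reason was the prior, whose degrees of freedom were estimated between 6.75 and 59.4 on version B where 8.2 had been simulated. With no simulated change, 8 of 20 draws of version B still gave calls, and 3 of 20 gave at least 11. A prior fitted by maximum likelihood kept the false share at 5.1% for version A and 5.09% for version B, and was added as an alternative after these values were seen. With it 81.3% of simulated 4-fold changes were called on version A and 96.2% on version B. On the real arrays this prior was estimated at 5.15 degrees of freedom on version A and 4.95 on version B. The noise of version B was simulated with 8.2. Its called shares and its calls without change may therefore not hold for the real arrays.

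Gene descriptions are those of the array files, mostly the best protein hit of each probe's sequence at the time, often from rice. Of 28830 probes on version A, 20619 had a description, and of 27097 on version B, 18395. Sequence names were looked up in the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, where 10 of 53747 matched, so the files' own names were kept and no coordinates are given. Named genes followed a fixed rule. It takes the 12 highest and 12 lowest mean log2 ratios past the test, filled where fewer passed from described probes at least 2-fold on both arrays. It adds up to 4 called members of each list or else its 2 brightest, and a fixed set of nitrate assimilation genes. Probes described only as hypothetical, by a clone or by an expressed tag were passed over, and so were repeats of a description.

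Version B repeated 380 probe IDs at spots of unrelated brightness (r = -0.05 across IDs), and another 380 IDs lay on both versions with unrelated brightness (r = -0.06). The 12 control probes shared by both versions correlated at 0.99. These ID sets stayed in the tests as planned, but they were left out of the gene lists and no gene was named from them, a choice made after the data were seen. A spot at or above 0.97 of its channel's maximum was treated as saturated. Where 1 channel was saturated on both arrays a fold is a lower bound, taken from each channel's mean after loess and Aquantile normalization and open to dye bias. It holds for that normalization, and is left out where median centring turned the sign or left the log2 ratio under 0.5, a rule chosen after the data were seen. Where both were saturated no fold is given. Alternatives covered background treatment, normalization, filters, the prior, the deposited ratios, a joint fit of both versions, thresholds and each replicate left out. Their effects stand in the closing section.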

Results

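The arrays compared the 2 sides of a divided maize root system 1 h after nitrate was given to one side only. Plants had grown for 6 days in 0.5 mM nitrate and 2 days without nitrogen. One side of the root then received 1 mM nitrate, and the other side stayed free of nitrogen, with 1 mM calcium chloride to balance the calcium. Root segments of 15 cm from the tip were taken at day 10. The comparison asks which transcripts respond to nitrate supplied locally. There were 2 arrays of version A and 2 of version B. The median intensity of maize probes lay between 1572.5 and 1939 in the nitrate channel and between 1438 and 1960 in the control channel, against a 95th percentile of blank spots of at most 242.4. Between 89.6% and 98.9% of probe spots exceeded the blank spots in the nitrate channel. The number of arrays limits the precision of every value.

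Genes for nitrate reduction, hemoglobins and enzymes of reductant supply were among the highest ratios in the nitrate-treated side. On version B, 11 probes passed the limma test, all of them higher with nitrate. Non-symbiotic hemoglobin 1 (MZ00040404), an oxygen- and nitric oxide-binding protein, had a log2 ratio of 3.39 ± 1.46 (SD, n = 2; limma adjusted p = 0.0364). Ferredoxin-nitrite reductase (MZ00016104), which reduces nitrite to ammonium, had 2.94 ± 0.49 (limma adjusted p = 0.00952). Uroporphyrin-III C-methyltransferase (MZ00036504), which makes the precursor of siroheme, the cofactor of nitrite reductase, had 2.82 ± 0.38 (limma adjusted p = 0.00952). Glutamate decarboxylase (MZ00029023), which makes gamma-aminobutyrate, had 2.84 ± 0.26 with the same limma adjusted p of 0.00952. A C2H2 zinc finger protein described as ZFP16 (MZ00046786) had 2.23 ± 0.20, and a tonoplast aquaporin (MZ00040544), a vacuolar water channel, had 2.16 ± 0.06, both at a limma adjusted p of 0.0263. The other 5 called probes fell outside the naming rule and are given after their values were seen. MZ00006197 is described as similar to the rice nodulin gene OsENOD93a, with 2.27 ± 0.46, and the rest (MZ00049544, MZ00054948, MZ00042562 and MZ00037142) have no informative description and log2 ratios from 1.98 to 2.47.

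On version A no probe passed the limma test, where the smallest adjusted p was 0.0697. At an unadjusted limma p under 0.05 there were 3415 of 28374 probes on version A and 3202 of 24748 on version B. In the simulation without any change, 5.43% of probes on version A and 5.49% on version B reached this on average. The calls on version B rest on the estimated prior: with a prior fitted by maximum likelihood, chosen after seeing the data, 0 probes passed on either version and the smallest adjusted p was 0.134 on A and 0.24 on B. The count was also 0 after plain background subtraction, which drops the normexp step and spots at or below 0, and with the deposited ratios. In the settings run for single genes, nitrite reductase, glutamate decarboxylase and uroporphyrin-III C-methyltransferase lost their calls in these 3. Their adjusted p there was 0.24 to 0.54 (limma, or the same moderated test with the maximum-likelihood prior). ZFP16 and the tonoplast aquaporin lost theirs there too, as none of the 11 probes stayed called. Hemoglobin 1 lost its call in 8 settings, with adjusted p from 0.0515 to 0.551 by the same tests. Of the 11 probes, 3 stayed called with print-tip loess and 4 with scaling between arrays. Simulated data of version B (24748 probes) without any change took their noise from the fitted limma prior. There 3 of 20 draws gave at least 11 calls.

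**Figure D1:**
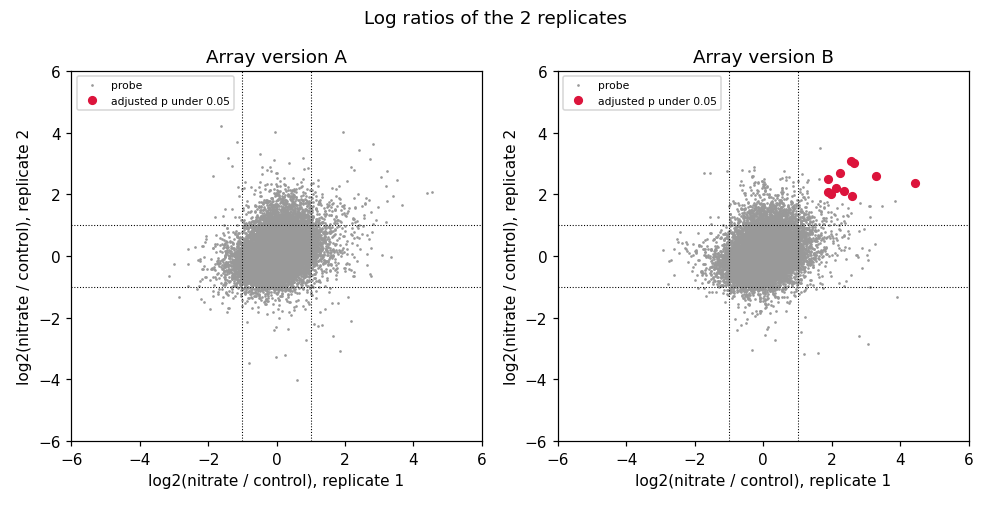
Each point is a probe, with the log2 ratio of nitrate over control on replicate 1 on the horizontal axis and on replicate 2 on the vertical axis, for version A (left) and version B (right). Dotted lines mark 2-fold and red points the 11 probes past the limma test, all in the upper right of version B.

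More probes were higher than lower with nitrate by at least 2-fold on both arrays. There were 168 higher and 36 lower probes on version A, and 146 higher and 14 lower on version B. With plain background subtraction there were 372 higher and 156 lower on version A, and 286 and 82 on version B. The excess was smaller on replicate 1, where that array alone had 746 higher and 634 lower on version A and 681 and 506 on version B, against 1379 and 272, and 1104 and 274, on replicate 2 alone. Opposite 2-fold ratios on the 2 arrays occurred for 35 probes on version A and 22 on version B. Among probes without a call, the highest ratios on version A belonged to a non-symbiotic hemoglobin probe (MZ00014313) with 3.31 ± 1.74 (SD, n = 2) and a plastid glutamine synthetase (MZ00014550) with 3.21 ± 1.66. A plastid glucose-6-phosphate dehydrogenase (MZ00024740), the entry enzyme of the oxidative pentose phosphate pathway, had 2.98 ± 0.35. A cytosolic 6-phosphogluconate dehydrogenase (MZ00015508) of the same pathway had 2.51 ± 1.02. On version B a nitrate reductase (MZ00040552) had 2.58 ± 1.31 and a probe described as anaerobically inducible early gene 2 (MZ00043272) had 2.55 ± 1.31. None of these 6 passed the limma test.

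No probe with a lower ratio passed the limma test on either version, so the 12 lowest are given as values. At an unadjusted limma p under 0.05 there were 1273 lower probes on version A and 1309 on version B, and with a trended robust prior 6 passed on version B. The lowest of those without saturation was a putative aminotransferase (MZ00011976) with a log2 ratio of -1.83 ± 0.14 (SD, n = 2). A cytochrome P450 (MZ00019833) had -1.71 ± 0.89. Alternative oxidase 1a (MZ00018270), a mitochondrial oxidase that bypasses part of the respiratory chain, had -1.58 ± 0.40. Mitochondrial ribosomal protein S3 (MZ00034732) was saturated in the control channel and at least 2.91-fold lower after loess, so it has no exact place among the 12. A MADS-domain protein (MZ00016147) had -1.48 ± 0.60 and the DNA-binding protein ABF1 (MZ00022254) had -1.44 ± 0.16. A beta-expansin (MZ00022872), a cell wall loosening protein, had -1.38 ± 0.41. An actin (MZ00030814) had -1.35 ± 0.36, and a chloroplast release factor (MZ00027977) had -1.34 ± 0.19. Mitochondrial ribosomal protein L16 (MZ00010837) had -1.32 ± 0.44, a probe described as PgPOR29 (MZ00036903) had -1.28 ± 0.16, and a multidrug resistance protein homolog (MZ00003042) had -1.26 ± 0.19.

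**Figure D2:**
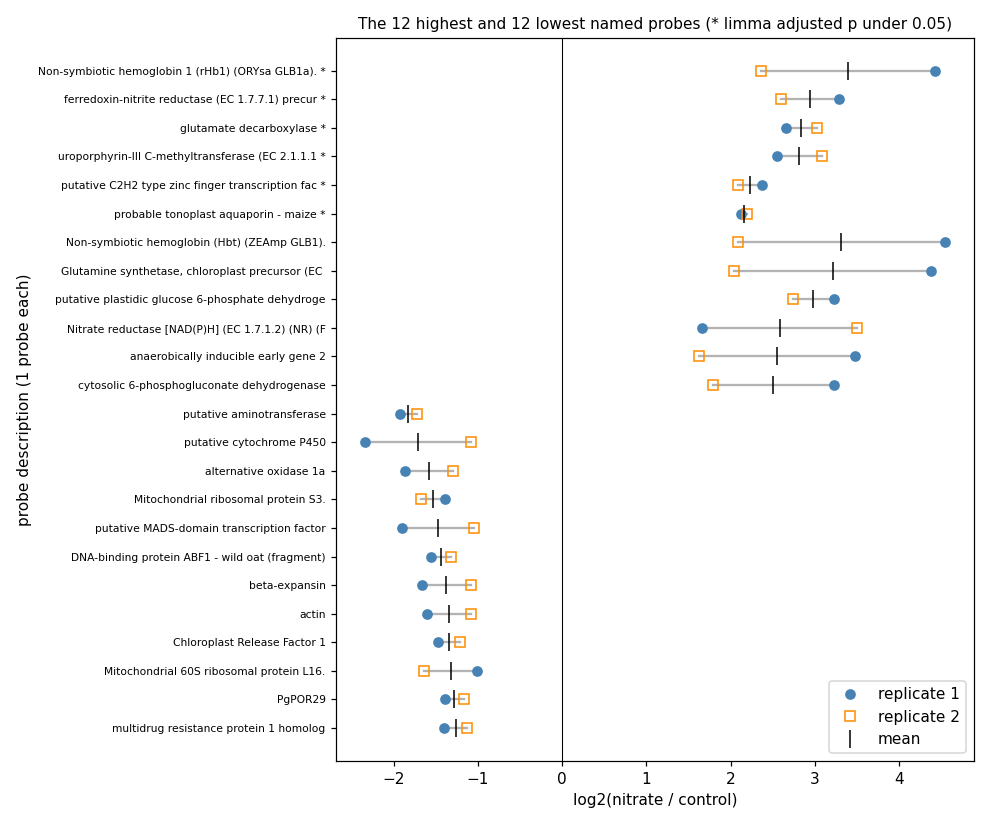
The horizontal axis gives the log2 ratio of nitrate over control for the 12 highest and 12 lowest named probes, with replicate 1 as filled circles, replicate 2 as open squares and the mean as a bar. Stars mark the 6 that passed the limma test. Both replicates lie on the same side of 0 for every probe shown, which the choice itself required for probes without a star.

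The nitrate reduction list rose as a group (camera adjusted p = 4.11e-07, 10 genes, median log2 ratio 0.91), a call lost at adjusted p = 0.794 with an estimated correlation. Of its members 1 passed the limma test over all probes, 5 were higher when adjusted over the list alone, and 4 were at least 2-fold higher on both arrays. The brightest nitrate reductase probe (MZ00019427) had 1.66 ± 0.04 (SD, n = 2) and the brightest nitrite reductase probe (MZ00016103) had 1.72 ± 0.10, neither past the limma test over all probes. Uroporphyrin-III C-methyltransferase on version A (MZ00016805) had 2.93 ± 0.29. The siroheme and molybdenum cofactor list missed the threshold (camera adjusted p = 0.0879), with 0 of its 11 members called over all probes and 3 higher adjusted over the list alone. The called uroporphyrin-III C-methyltransferase probe MZ00036504 shares its protein hit with the brighter MZ00016805, which stands for the gene in the list. The molybdopterin synthase CNX2 (MZ00015623) had 0.77 ± 0.57 and did not pass over the list alone, while another CNX2 probe (MZ00029209) had 1.18 ± 0.71 and did.

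Ammonium assimilation genes also rose as a group (camera adjusted p = 0.000193, 20 genes, median 0.46). This call was lost at adjusted p = 0.794 with an estimated correlation. No member passed the limma test over all probes, and 8 were higher adjusted over the list alone. Members differed in direction. The glutamine synthetase probe with the highest mean log2 intensity (MZ00043860) had -0.67 ± 0.47 (SD, n = 2), while another (MZ00043252) had 1.32 ± 1.17. Ferredoxin-dependent glutamate synthase (MZ00015060) had 1.42 ± 0.42. The brightest asparagine synthetase probe (MZ00014557) had 0.13 ± 0.07, and its sign turned with median centring to -0.21. Other probes of this enzyme ranged from -0.61 ± 0.19 (MZ00049532) to 0.92 ± 0.47 (MZ00034199).

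The reductant supply list, of pentose phosphate pathway enzymes and ferredoxins, rose as a group (camera adjusted p = 0.0119, 33 genes, median 0.24), again lost at adjusted p = 0.794 with an estimated correlation. None of its members passed over all probes and 4 were higher adjusted over the list alone. Ferredoxin VI (MZ00017025), an iron-sulfur electron carrier, had 1.81 ± 0.24 (SD, n = 2). The root isozyme of ferredoxin-NADP reductase (MZ00026842) was saturated in the nitrate channel and at least 3.32-fold higher after loess (log2 ratio 1.73, or 1.33 with median centring). Sulfite reductase (MZ00014813) was likewise saturated, with a log2 ratio of 0.76 after loess and 0.32 with median centring, so no bound is given. The brightest glucose-6-phosphate dehydrogenase probe (MZ00024075) had 0.04 ± 0.74 and turned to -0.32 with median centring. The brightest 6-phosphogluconate dehydrogenase probe (MZ00024050) was saturated in both channels.

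Hemoglobin, hypoxia, aquaporin and organic acid lists rose as well, and each of these 4 calls was lost at adjusted p = 0.794 with an estimated correlation. For hemoglobin the camera adjusted p was 6.56e-05 over 3 protein hits, of which 1 was called over all probes and 3 adjusted over the list alone. Whether the non-symbiotic hemoglobin probes of versions A and B detect separate genes was not tested. The other member is a 2-on-2 hemoglobin (MZ00016571) with 0.56 ± 0.01 (SD, n = 2) and a limma p of 0.0417, both unadjusted and adjusted over the list alone. The hypoxia list (camera adjusted p = 0.000435, 42 genes, median 0.32) holds alcohol dehydrogenases and pyruvate decarboxylases, and its pattern also takes cinnamyl alcohol dehydrogenases, enzymes of lignin synthesis. Its call was also lost with all probes of each gene (adjusted p = 0.0814) and on version B alone (0.0571). None of its members was called over all probes, and 6 were higher adjusted over the list alone, all described as alcohol dehydrogenases, the last enzyme of ethanol fermentation. Most of these are described as alcohol dehydrogenase 1 or I, or as 2 or II. Camera counts them as separate genes, and whether they detect separate genes was not tested. The highest was alcohol dehydrogenase 1 (MZ00013561) with 2.14 ± 0.64. Its 2 brightest members were an alcohol dehydrogenase (MZ00040414) with 0.75 ± 0.90 (SD, n = 2) and a pyruvate decarboxylase (MZ00035896) with 0.06 ± 0.04, which turned to -0.33 with median centring. Among aquaporins (camera adjusted p = 0.00874, 9 genes, median 0.26) none was called in the list's own probes and 3 were higher adjusted over the list alone. The called tonoplast aquaporin shares its protein hit with a brighter probe, which stands for the gene in the list. That probe (MZ00042389) was saturated with nitrate, and its log2 ratio turned from 0.34 to -0.0638 with median centring, so no bound is given. Organic acid metabolism (camera adjusted p = 0.0161, 53 genes, median 0.13) had 0 members called either way. Its brightest members were a malate dehydrogenase (MZ00043236) with -0.09 ± 0.01 and phosphoenolpyruvate carboxylase (MZ00023938) with 0.29 ± 0.11, the latter -0.15 with median centring.

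All 7 list calls thus rest on the preset correlation of 0.01, where the camera p does not measure the spread between replicates. With 2 replicate columns, camera with an estimated correlation has 1 residual degree of freedom and little power. Its unadjusted camera p for nitrate reduction was 0.107, against 1.52e-08 with the preset correlation. The losses with an estimated correlation therefore do not decide for or against the calls. With median centring in place of loess, camera also lost ammonium assimilation (adjusted p = 0.0663), reductant supply (0.402), organic acid metabolism (0.853) and aquaporins (0.0615). On version B alone ammonium assimilation (0.11), reductant supply (0.0571) and hypoxia were lost, on version A alone organic acid metabolism (0.329) and aquaporins (0.262), and with deposited ratios, a setting chosen after seeing the data, reductant supply (0.201).

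**Figure D3:**
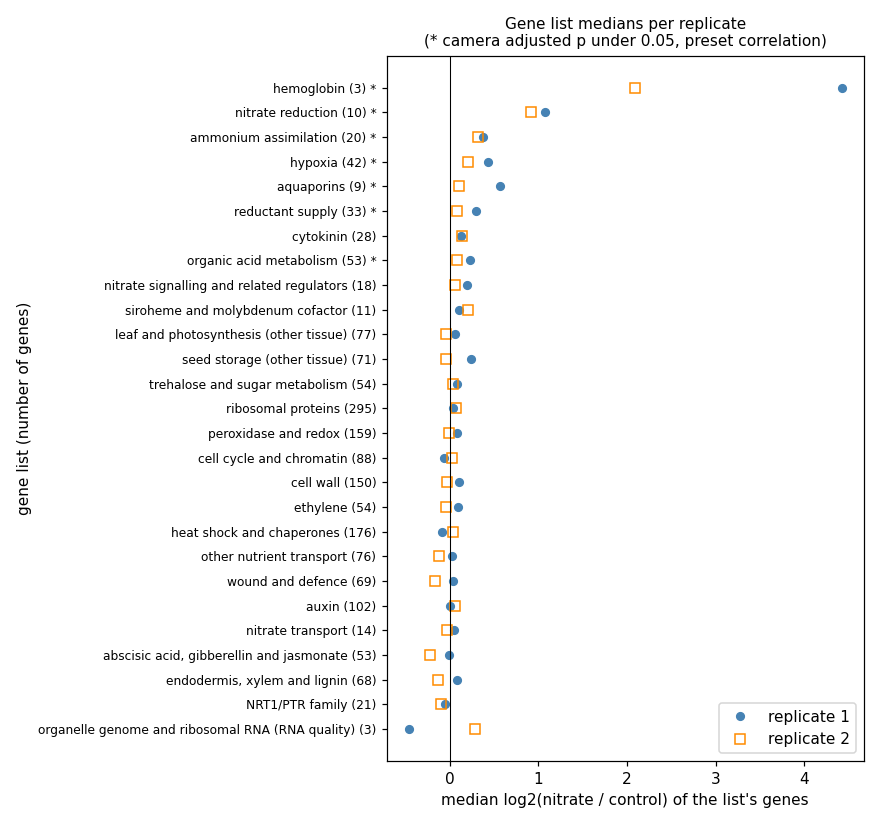
The horizontal axis gives the median log2 ratio of nitrate over control of the genes of each list, and the vertical axis the 27 lists with their number of genes. Replicate 1 is a filled circle and replicate 2 an open square, and stars mark the 7 lists past the camera test with the preset correlation.

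The remaining 20 lists did not pass in the main camera test. Nitrate transport had a median of -0.06 over 14 genes (camera adjusted p = 0.877), although the camera direction, which is relative to all other genes, was up. A putative high affinity nitrate transporter (MZ00022068) had 1.59 ± 1.27 (SD, n = 2), and another putative nitrate transporter (MZ00003010) had 0.10 ± 0.37 and turned to -0.28 with median centring. No probe was described as the transporter partner NAR2 or NRT3. The NRT1/PTR family had a median of -0.19 (camera adjusted p = 0.58), with 2 peptide transporters (MZ00017748 and MZ00017869) at -0.19 ± 0.20 and -0.25 ± 0.31. Among nitrate signalling regulators (camera adjusted p = 0.529), a CIPK-like protein (MZ00024420) had 0.55 ± 0.19 and LOB domain protein 12 (MZ00047827) had 0.38 ± 0.03, the latter -0.0195 with median centring. Cytokinin genes had a camera adjusted p of 0.159 over 28 genes, where 2 were higher adjusted over the list alone, and the response regulator Cip1 (MZ00040804) had 0.36 ± 0.16, or -0.0345 with median centring.

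Auxin genes (camera adjusted p = 0.529), ethylene genes (0.891), abscisic acid, gibberellin and jasmonate genes (0.44) and trehalose and sugar genes (0.44) did not pass. The ethylene list also takes names with methylene in them. IAA2 (MZ00036930) had 0.12 ± 0.05 (SD, n = 2), or -0.28 with median centring, and an ethylene-responsive coactivator (MZ00052447) had 0.49 ± 0.28. Adjusted p from camera was 0.529 for cell wall genes, 0.418 for peroxidase and redox genes, 0.891 for other nutrient transport, 0.801 for ribosomal proteins (a shift down at 0.0277 with median centring), 0.891 for cell cycle and chromatin and 0.937 for heat shock. Cellulose synthase-2 (MZ00014529) had 0.10 ± 0.12, or -0.34 with median centring, and a mitochondrial phosphate transport protein (MZ00040097) had -0.09 ± 0.41. Wound and defence genes had 0.891 and endodermis, xylem and lignin genes 0.688. A phenylalanine ammonia-lyase (MZ00049296) had 0.12 ± 0.02 and another (MZ00014291) 0.28 ± 0.41, or -0.29 and -0.15 with median centring. Markers of other tissues did not pass either, with a camera adjusted p of 0.416 for leaf and photosynthesis and 0.252 for seed storage. A Rubisco small chain (MZ00005992) had -0.71 ± 1.06. The list meant for RNA quality held only 3 genes, all described as a lyase acting on ribosomal RNA, with a camera adjusted p of 0.891, so it says nothing of RNA quality. Nearly all other brightest members of these lists were saturated in the control channel or in both. Median, mean and test differed in sign for nitrate transport, for auxin (median -0.01, mean 0.05, test up), for ethylene (median 0.00088, mean -0.0087, test up) and for cell cycle and chromatin (median 0.02, mean -0.02, test down).

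The 2 replicates correlated weakly across probes, which are not independent replicates. Pearson's r was 0.29 and Spearman's rho 0.30 on version A, and 0.27 and 0.28 on version B. With median centring Pearson's r was 0.42 on version A and 0.44 on version B. For 583 sequences with a probe on each version, r was 0.23 and 0.16 between replicates within a version, and -0.02 and -0.02 between replicates on different versions, where the probe differs. Different probes of a gene could disagree: of 138 protein hits with several probes of which 1 was at least 2-fold higher on both arrays, 64 had another probe with a mean below 0.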

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

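Control spots outside the maize probes gave signal above the buffer and blank spots in both channels of all 4 arrays. Among the control oligos, whose sequences are not explained in the files, 17 sets did so and the highest median intensity was 73915. The spots named Alien reached a median of at most 754.5. No biological explanation was tested for either.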

How the results depend on the processing

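No paired analysis was possible because within a version each replicate number has 1 array, apart from the pairing of both root sides on every array that the ratios already hold and the joint fit that stacks versions by replicate number. An alternative with no background removed at all was not run, since the deposited intensities are already background-subtracted. Plain subtraction used these intensities as they are, without the further normexp step, and left out spots at or below 0 in either channel. Brightness of at least 800 in both channels, saturated probes or recurring IDs left out, the maximum-likelihood prior, and 4 of the camera settings (print-tip loess, plain subtraction, deposited ratios, strict filter) were chosen after seeing the data. The cause of each difference was not tested, except that looser thresholds count more probes by construction.

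Version A had 0 probes past the test and 8 with print-tip loess, 2 with scaling between arrays, 4 with the trended robust prior, 4 in the joint fit, 3 at brightness 800, 11 at adjusted p 0.1, 3415 at unadjusted p 0.05 and 898 at 0.01. Version B had 11, and 0 with plain subtraction, deposited ratios or the maximum-likelihood prior, 3 with print-tip loess or the joint fit, 4 with scaling, 19 with median centring, 23 with the strict filter, 71 with the trended robust prior (65 higher, 6 lower), 33 at brightness 800, 69 at adjusted p 0.1, 3202 at unadjusted p 0.05 and 992 at 0.01. Of the 11 probes, 10 stayed called with median centring, 3 with print-tip loess and 4 with scaling.

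Version A had 204 probes at least 2-fold the same way, and 528 with plain subtraction (372 higher, 156 lower), 350 with median centring (279 higher, 71 lower), 630 with deposited ratios (546 higher, 84 lower), 101 at brightness 800, 1299 at 1.5-fold and 39 at 3-fold. Version B had 160, and 368 (286 higher, 82 lower), 381 (314 higher, 67 lower), 358 (314 higher, 44 lower), 92, 1103 and 27 under the same settings. On a single array the count was 1380 to 1651 for version A and 1187 to 1378 for version B. The excess of higher probes differed between arrays: replicate 2 alone had 1379 higher and 272 lower on version A, and replicate 1 alone had 746 and 634. The replicate correlation moved with median centring to 0.42 on version A and 0.44 on version B.

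The number of lists past camera was 7, and 0 with an estimated correlation and 3 on version B alone. In 5 combinations of list and setting, a list that had not passed did pass in the same direction. With an estimated correlation each of the 7 lists had an adjusted p of 0.794, in a camera test with 1 residual degree of freedom and little power. Ammonium assimilation was lost on version B alone (0.11) and with median centring (0.0663). Reductant supply was lost on version B alone (0.0571), with median centring (0.402) and with deposited ratios (0.201). Organic acid metabolism was lost on version A alone (0.329) and with median centring (0.853), aquaporins on version A alone (0.262) and with median centring (0.0615), and hypoxia with all probes of each gene (0.0814) and on version B alone (0.0571). Nitrate reduction and hemoglobin passed in every setting that could test them except the estimated correlation. Ribosomal proteins turned with median centring to a shift down (adjusted p = 0.0277).

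With median centring 13 named genes without a call changed sign: asparagine synthetase (-0.21), glucose-6-phosphate dehydrogenase MZ00024075 (-0.32), nitrate transporter MZ00003010 (-0.28), phosphoenolpyruvate carboxylase (-0.15), LOB domain protein 12 (-0.0195), IAA2 (-0.28), Cip1 (-0.0345), cellulose synthase-2 (-0.34), aquaporin MZ00042389 (-0.0638), pyruvate decarboxylase (-0.33), MZ00036644 of the defence list (-0.33) and the phenylalanine ammonia-lyases (-0.29 and -0.15). At least 89.6% of spots exceeded the blanks, but of the probes 2-fold higher on both arrays, 90 of 168 on version A and 79 of 146 on version B stayed so at brightness 800, as did 7 of the 11 calls.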

Other observations

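The dye-effect, low-oxygen, nitrate-response, measurement-noise and probe-effect tests were chosen after the result was seen, while the dim-spot and block tests were set before. The bounds of the nitrate-response, noise and probe-effect tests were set after related values had been seen. The bootstrap intervals and the permutation p below resample sequences or genes within these arrays. They do not measure the spread between replicates.

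Adjusted over the list alone, which does not cover the other lists, other transcripts were higher on both arrays without a call over all probes. Cytokinin oxidase 2 (MZ00031342), which degrades cytokinins, had a log2 ratio of 1.35 ± 0.30, and response regulator 4 (MZ00036348), of the cytokinin pathway, had 0.97 ± 0.15 (SD, n = 2). Sucrose synthase 2 (MZ00013609) had 1.92 ± 0.40. The molybdenum cofactor protein Cnx1 (MZ00027992) had 0.93 ± 0.28. Of the nitrate signalling regulators, CBL-interacting protein kinase 23 (MZ00005879) was the 1 that was lower adjusted over the list alone, with -1.07 ± 0.07.

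More probes were higher than lower by 2-fold on both arrays. Dim spots as the source are argued against by the probes with both channels at 800 or more, where the share of higher ones was 0.88 (95% exact interval 82.1% to 91.9%, 169 higher and 24 lower). That interval counts probes as independent and does not measure the spread between replicates. A fixed dye effect stays open and cannot be told apart from the treatment, since every array had nitrate in Cy3; the share over all probes was 0.86.

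Of the 42 members of the hypoxia list, 6 probes described as alcohol dehydrogenases were higher adjusted over the list alone and none over all probes. These 6 may not detect separate genes. Lower oxygen on the nitrate side is a candidate explanation. A list of 49 other glycolytic and low-oxygen genes, without those already seen to be high, shifted up in limma's camera test (adjusted p = 0.000639, equal to the unadjusted value because 1 list was tested). This was lost at an adjusted p = 0.426 with an estimated correlation, chosen after seeing the data and of little power with 1 residual degree of freedom. Their median was 0.27 on replicate 1 and -0.01 on replicate 2, and the explanation needed both above 0. The nitrate response moving both groups by 1 factor also stays open: replicate 1 minus replicate 2 differed between the 42 hypoxia genes and 30 assimilation genes by 0.13 in the median (bootstrap interval -0.35 to 0.45, permutation p = 0.405), inside a bound of 0.5 that is wide beside the medians of 0.24 and 0.11.

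The 2 replicates agreed weakly across probes, with r of 0.29 and 0.27 after loess and 0.42 and 0.44 with median centring. Array noise alone is argued against by 583 sequences with a probe on each version, which correlated at 0.39 and 0.43 between versions at one replicate number and at 0.23 and 0.16 between replicates within a version, a difference of 0.22 (bootstrap interval 0.09 to 0.34). Uneven hybridisation over blocks is argued against because loess within blocks changed the correlation by at most -0.022. Between versions at different replicate numbers the same sequences correlated at -0.02 and -0.02, lower than within a version by 0.21 (bootstrap interval 0.15 to 0.28). The agreement of the replicates in these sequences was thus absent once the probe changed. A fixed effect of each probe, of the dye or of hybridisation, would give this, and stays open for the agreement across all probes. Probes of one sequence that detect different transcripts stay open too, since their brightness correlated between versions at only 0.39 and 0.42. The replicates did differ in a way that both versions shared, as these sequences correlated at 0.39 and 0.43 at one replicate number against -0.02 and -0.02 at different numbers. Whether that difference lies in plants, extraction or labelling was not tested.

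The 12 maize control probes spotted repeatedly on both versions correlated at 0.90 and 0.97 between versions at one replicate number, at -0.02 and 0.25 between replicates within a version, and at -0.02 and 0.19 between versions at different replicate numbers.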
